A study of Mus musculus with 17 samples.

How the data were processed

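Total RNA of 17 samples described as ovary was hybridised to Illumina MouseWG-6 v2.0 arrays as biotin-labelled cRNA. The samples came from adult female mice of a FVB/N and C57/BL6 cross, taken at an age of 12 weeks. The labels give 4 genotypes: wild type (4 arrays), an Fshr mutant called Fshr-CAM (4), Lhr-null (4) and Fshr-CAM/Lhr-null (5). The meaning of the abbreviation CAM is not given in the sources used here. Genotypes were read from the labels and replicate numbers from the column names, and 0 signal columns were left without a sample.

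The deposited values were made by the authors in GenomeStudio 1.7.0, per the submitters' processing notes. The deposited non-normalised table gives for each of 45281 probes, per the file headers, an average signal intensity without background subtraction. It also gives, per the file headers, a detection p-value for each probe and array, and the number of beads behind each deposited signal. A further deposited table holds the same intensity values after quantile normalisation by the authors. The deposited series matrix holds intensity values identical to that table, with a largest difference of 0. Per array, 19366 to 22006 probes had a detection p under 0.05, the median signal was 56.7 to 74.4, and the median number of beads per probe was 41 to 43.

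Values were computed from the non-normalised table with neqc of limma 3.58.1 in R 4.3.3, which corrects background with the detection p-values, adds an offset of 16, normalises by quantiles and takes log2. A probe was kept with a detection p under 0.05 on at least 4 arrays, which left 23311 probes, of which 19615 carried a single gene symbol. Of all probes, 34885 had 1 symbol, 18 several and 10378 none in the array annotation; probes with several or none were left out. Of the named probes 34807 matched a gene identifier in the GRCm38.p6 annotation, used here for names only, 78 did not, and 0 symbols were updated. Each gene was represented by its brightest kept probe, which left 12260 genes. No probe carries the symbol Lhcgr, so the Lhr transcript itself was not analysed here.

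Log2 values were fitted with 1 mean per genotype by limma, with eBayes and an intensity trend, and adjusted p-values are from the Benjamini-Hochberg method with a threshold of 0.05. The 6 comparisons were Fshr-CAM against wild type, Lhr-null against wild type, Fshr-CAM/Lhr-null against Lhr-null, against Fshr-CAM and against wild type, and the interaction, which subtracts the Fshr-CAM effect with Lhr from that without. The groups, comparisons, gene lists, alternatives and rule for named genes were set before the data were examined, except where stated. In addition to all 17 arrays, fits were made on 16 arrays without the array labelled Lhr-null replicate 1 (12137 genes), 15 arrays also without the array labelled Fshr-CAM/Lhr-null replicate 4 (12074 genes) and 14 arrays also without Lhr-null replicate 2 (12000 genes). Leaving out single arrays was planned; using the 16-array fit for gene values, and the 15-array and 14-array fits, were chosen after the data were seen. Each fit was normalised on its own arrays.

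Genes are named by a rule. Fshr and Lhcgr are always named where measured. Each comparison except Fshr-CAM/Lhr-null against wild type names the 6 largest rises and 6 largest falls past the threshold whose arrays do not overlap between the groups, where for the interaction the threshold alone applies, leaving out clone and predicted names. Each list names up to 2 members with the largest change past the threshold. The rule was applied to the 17-array, 16-array and 15-array fits and named 100 genes, and other genes named are marked as chosen after their values were seen. Where every array of a group lay at background, the fold is a lower bound, written as at least; against a group with some arrays at background, and for the interaction, values depend on the background. Pituitary, Y-linked and most sperm genes, and Ovgp1, were named after their values were seen.

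The 21 gene lists, written by hand from general knowledge, were granulosa cell, theca and interstitial cell, corpus luteum, steroid hormone synthesis, cholesterol synthesis and uptake, LH-responsive ovulation and cumulus expansion, oocyte, Sertoli cell, macrophage, lymphocyte, red blood cell, endothelial cell, smooth muscle, ovarian surface epithelium, oviduct and ciliated epithelium, adipocyte, extracellular matrix, cell proliferation, cAMP response and immediate early, heat shock and stress, and interferon response. They were tested with camera of limma at a preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over all lists and comparisons. Counts adjusted over the list alone are also given. Pituitary, spermatid and Y-linked lists were added after the data had been seen.

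Alternatives were the authors' quantile-normalised values, the series matrix, median-centred signals without background correction, no detection filter, a stricter filter (detection p under 0.01 on every array of a genotype), the mean of a gene's probes, array quality weights without a trend, the replicate number as a block, only the arrays of the groups compared, and leaving out each array in turn. Other splits of the samples, up to 100 per comparison, were counted for chance; for the interaction, residuals of a fit without it were reassigned among the arrays. Arrays far from their group were found with Dixon's test. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3.

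The fit was tested on simulated data of 12260 genes with 200 changed. With 17 arrays it recovered 71 to 82 of 100 genes changed by 1 on the log2 scale and 96 to 100 of 100 changed by 2, over 4 comparisons, with at most 15 false calls among 200. With 16 arrays it recovered 68 to 78 and 93 to 100, with at most 14 false calls among 198. Both simulations drew each gene's spread from the fit without Lhr-null replicate 1, independently between genes and arrays. The 17-array values therefore leave out the spread that Lhr-null replicate 1 adds to the real 17-array fit.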

Results

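RNA from samples described as mouse ovary was measured on 17 arrays. The design crosses an Fshr mutant genotype, called Fshr-CAM in the labels, with loss of Lhr. Fshr and Lhr are the receptors of FSH and LH, the pituitary hormones that drive follicle growth, ovulation and luteal function. There were 4 wild type, 4 Fshr-CAM, 4 Lhr-null and 5 Fshr-CAM/Lhr-null arrays. Per array, 19366 to 22006 of the 45281 probes were detected at p under 0.05, with a median of 41 to 43 beads per probe, and the number of arrays limits the precision. The labels do not say that each sample came from a separate animal, so the p-values measure only the spread between these samples.

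The array labelled Lhr-null replicate 1 carried pituitary hormone genes near the top of the signal range. Growth hormone (Gh), prolactin (Prl) and the LH beta subunit (Lhb) had log2 signals of 14.90, 14.71 and 14.40 there, while the mean of the pituitary list stood at 10.87 on this array and at 4.44 to 4.61 on the other 16. Its granulosa cell list mean was 6.41, against 9.25 to 9.57 on the other 3 Lhr-null arrays, and its oocyte list mean was 5.49, against 8.83 to 9.06. Pearson's r across 13297 probes, which are not independent replicates, was 0.799 to 0.827 between this array and the others, and 0.918 to 0.988 among the other 16.

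Other arrays also differed from their group. On the array labelled Lhr-null replicate 2, the sperm genes Ldhc, a testis lactate dehydrogenase, and Prm1, a protamine, stood at 13.30 and 12.15. The oviduct glycoprotein Ovgp1 stood at 11.30 and 13.33 on Lhr-null replicates 3 and 4, at 10.46 on Fshr-CAM/Lhr-null replicate 3, and at most at 7.42 on wild type and Fshr-CAM arrays. On the array labelled Fshr-CAM/Lhr-null replicate 4, Fshr stood at 9.71, against 11.40 to 11.70 on the other 4 of its group. Counts of genes are therefore given from all 17 arrays, from 16 arrays (without Lhr-null replicate 1) and from 15 arrays (also without Fshr-CAM/Lhr-null replicate 4). Values of genes and lists come from the 16-array fit unless another is named, a choice made after the data were seen.

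**Figure D1:**
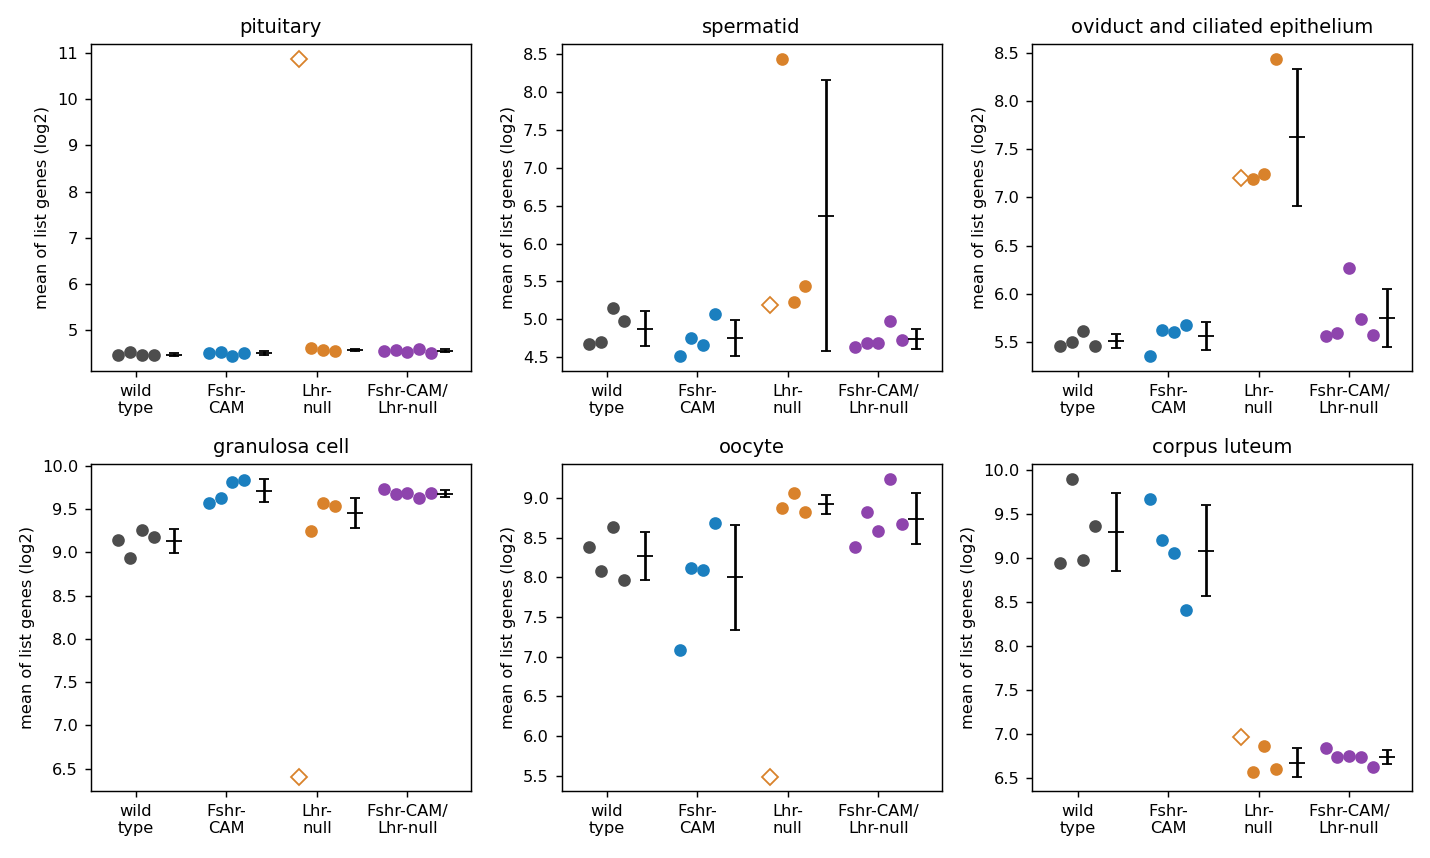
Mean normalised signal (log2, vertical axis) of 6 gene lists on each array by genotype; each point is 1 array, the open diamond is the array labelled Lhr-null replicate 1, and the bar and whiskers are the mean and SD of the group's other arrays. The pituitary list stands at 10.87 on that array and at 4.44 to 4.61 on the other 16, and the spermatid list at 8.44 on Lhr-null replicate 2.

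Fshr-CAM against wild type asks what the Fshr mutation changes in the ovary while Lhr is present. Fshr itself, the FSH receptor of granulosa cells, was 6.64-fold higher in Fshr-CAM than in wild type at probe ILMN_1228881 (log2 signal 11.52 ± 0.32 against 8.79 ± 0.36, SD, n = 4 and 4; limma log2 fold change 2.73 ± 0.35 SE, Benjamini-Hochberg adjusted p = 0.00248). Rhox8, a homeobox gene of gonadal somatic cells, rose 9.43-fold (3.24 ± 0.47, adjusted p = 0.00755). Inhba, which encodes the beta A subunit of activin and inhibin in granulosa cells, rose 3.81-fold (1.93 ± 0.21, adjusted p = 0.000907). Adcyap1, which encodes the neuropeptide PACAP, fell at least 4.91-fold (−2.62 ± 0.43, adjusted p = 0.0143), with its probe at background on every Fshr-CAM array.

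Further genes that rose in Fshr-CAM included Cracd, an actin regulator (2.26 ± 0.30), Fam162b (2.13 ± 0.36) and Ddc, the aromatic amino acid decarboxylase (1.86 ± 0.29). Atp12a, a proton pump subunit (−1.70 ± 0.27), Pcsk5, a proprotein convertase (−1.43 ± 0.23), and Tmem200a (−1.04 ± 0.20) fell. Pcsk5 has 3 probes, which ranged from −1.43 to 0.11. With all 17 arrays, Cracd, Enc1 and Ddit4 rose and Adcyap1, Atp12a and Pcsk5 fell among 12260 genes, with 375 at an unadjusted p under 0.05. With 16 arrays, 21 genes rose and 4 fell of 12137, and with 15 arrays 38 rose and 5 fell of 12074. Among the fits that each left out 1 of the 17 arrays, those without wild type replicate 2 and without Fshr-CAM replicate 4 had 1 higher and 0 lower genes. Leaving out Fshr-CAM replicate 2 or 3 also gave 0 lower genes. So did leaving out Fshr-CAM/Lhr-null replicate 1, 2, 3 or 5, or Lhr-null replicate 3 or 4. Fshr did not pass in the 17-array fit (2.73 ± 0.85, adjusted p = 0.972).

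Of the other Fshr probes, ILMN_2736929 rose (2.09 ± 0.35, adjusted p = 0.0213) and ILMN_2932141 was not past the threshold (0.11 ± 0.23, adjusted p = 1). Which part of the transcript each probe reads was not analysed here.

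**Figure D2:**
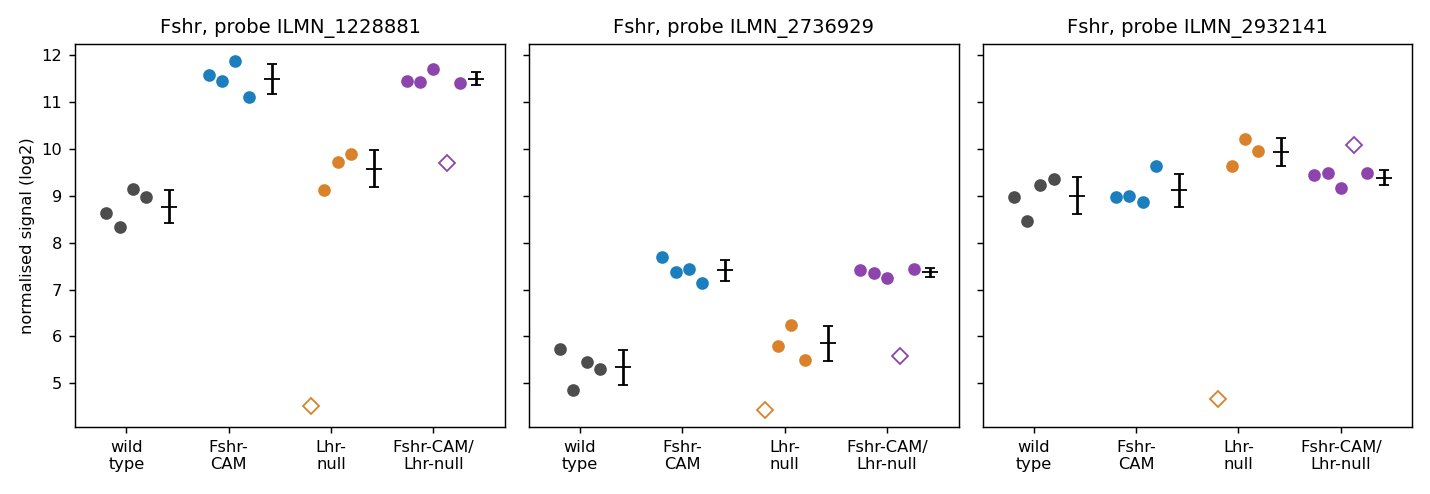
Normalised signal (log2, vertical axis) of 3 Fshr probes on each array in 4 genotypes; points are arrays, open diamonds are the arrays labelled Lhr-null replicate 1 and Fshr-CAM/Lhr-null replicate 4, and bars and whiskers are the mean and SD of the group's other arrays. Probe ILMN_1228881 lies at 11.10 or above on the 4 Fshr-CAM arrays and at 9.14 or below on the 4 wild type arrays.

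Granulosa cell genes were higher in Fshr-CAM as a list. Of 15 measured, 3 rose (Fshr, Inhba and Inha, the inhibin alpha subunit, 0.82 ± 0.13) and 6 were higher adjusted over the list alone. Their median was 0.29, with camera adjusted p = 1.1e-10 and adjusted p = 0.00398 with an estimated correlation. The granulosa cell list includes Fshr, the gene that the genotype alters, and was not tested without it. The same holds for every comparison of the Fshr mutation below. Rhox5, a homeobox gene of the Sertoli cell list, rose by 1.16 ± 0.19 (adjusted p = 0.0143); the median of the 9 measured genes of that list was −0.16 while its camera direction was up (adjusted p = 0.401).

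Genes of cholesterol synthesis and uptake, which feed steroid production, lay lower in Fshr-CAM. Of 18 measured, 0 passed in limma over all genes and 11 were lower adjusted over the list alone, with a median of −0.61 and none above 0. Camera gave adjusted p = 5.34e-13, which was not kept with an estimated correlation (adjusted p = 0.0773 with an estimated correlation). Of 10 corpus luteum genes, 1 fell (Pcsk5, with 2 lower adjusted over the list alone, median −0.24, camera adjusted p = 0.0511). Of 12 steroid hormone synthesis genes, 0 passed (median −0.15, camera adjusted p = 0.453).

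For other lists camera passed at the preset correlation, without a called gene in limma and not with an estimated correlation. The median of 23 oocyte genes was −0.34 (camera adjusted p = 0.0024, adjusted p = 0.639 with an estimated correlation). The list mean was 7.09 on Fshr-CAM replicate 1 and 8.10 to 8.69 on the other 3, against 7.97 to 8.64 in wild type, and without Fshr-CAM replicate 1 the median of list oocyte, Fshr-CAM against wild type, was 0.05 in the 17-array fit. The median of 8 smooth muscle genes was 0.38 (camera adjusted p = 0.000144, adjusted p = 0.306 with an estimated correlation). The medians of 12 heat shock genes and 6 adipocyte genes were both 0.30, with camera adjusted p of 0.0162 and 0.0402, and adjusted p = 0.34 and 0.208 with an estimated correlation.

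Lhr-null against wild type asks what loss of the LH receptor changes in the ovary. Akr1c18, the luteal enzyme that inactivates progesterone, fell 107-fold (log2 signal 5.93 ± 1.09 in Lhr-null against 12.68 ± 2.17 in wild type, SD, n = 3 and 4; log2 fold change −6.75 ± 0.93 SE, adjusted p = 0.000301), and 43.9-fold with all 17 arrays (−5.46 ± 1.16, adjusted p = 0.0092). Star, which carries cholesterol into mitochondria for steroid synthesis and was detected on 2 of 3 Lhr-null arrays, fell (−4.86 ± 0.47, adjusted p = 1.74e-05). Cyp11a1, the side-chain cleavage enzyme that follows it, fell by 2.69 ± 0.32 on the log2 scale (adjusted p = 0.000102). The luteal prostaglandin F receptor Ptgfr fell at least 9.08-fold (−3.66 ± 0.35, adjusted p = 1.65e-05).

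Other large falls in Lhr-null were of the transporter Abcb1b (43.2-fold, −5.43 ± 0.44), the transcription factor Onecut2 (at least 40.4-fold, −5.71 ± 0.89), Ssu2 (−4.81 ± 0.91) and the Wnt ligand Wnt10b (at least 15.5-fold, −4.36 ± 0.30). The sterol enzymes Dhcr7 and Hsd17b7 fell 9.02-fold (−3.17 ± 0.36) and 8.43-fold (−3.08 ± 0.45). The largest rises were of Dynlrb2, a dynein light chain of cilia (34.2-fold, 5.10 ± 0.50, adjusted p = 1.74e-05), the cardiac myosin Myh6 (at least 14.3-fold, 4.38 ± 0.47), Prm1 (3.85 ± 0.98, adjusted p = 0.019) and the cilia genes Pifo (3.75 ± 0.33), Dnali1 (3.71 ± 0.36) and Cfap299 (at least 9.78-fold, 3.67 ± 0.35). Fshr at probe ILMN_1228881 was not past the threshold with 16 arrays (0.81 ± 0.37, adjusted p = 0.164) and was with 15 (0.82 ± 0.22, adjusted p = 0.0225), a fit that leaves out Fshr-CAM/Lhr-null replicate 4 because of its low Fshr. With 16 arrays, in limma over all kept probes, Fshr probe ILMN_2932141 was higher (0.93 ± 0.24, adjusted p = 0.025). Probe ILMN_2736929 was not past the threshold there (0.52 ± 0.38, adjusted p = 0.429).

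Of 12260 genes, 314 rose and 547 fell in the 17-array fit, which includes Lhr-null replicate 1 with its pituitary genes. Without Lhr-null replicate 1, 668 rose and 837 fell of 12137 genes, of which 753 were also called with all 17 arrays. In the 16-array fit 265 of the higher and 341 of the lower genes changed by over 2-fold. With 15 arrays 784 rose and 896 fell. Leaving out wild type replicate 1, 2, 3 or 4 or Lhr-null replicate 4 from the 17 arrays gave 202, 146, 192, 191 and 208 higher genes, and without wild type replicate 2 there were 315 lower genes.

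Luteal and steroid genes were among those that fell. Of 10 corpus luteum genes 8 fell, 8 also adjusted over the list alone, with a median of −2.88 (camera adjusted p = 4.46e-08, and adjusted p = 0.00529 with an estimated correlation). Of 12 steroid hormone synthesis genes 7 fell and 1 rose, Hsd17b1, the granulosa cell enzyme of estradiol synthesis (1.07 ± 0.24, adjusted p = 0.0093); the list's median was −1.13 (camera adjusted p = 7.43e-06, and adjusted p = 0.0291 with an estimated correlation). Of 18 cholesterol genes 12 fell, and 16 adjusted over the list alone (median −1.32, camera adjusted p = 1.58e-11, and adjusted p = 0.104 with an estimated correlation). Among 16 genes of the cAMP and immediate early response, through which LH acts, 7 fell, led by the phosphatase Dusp1 (−2.69 ± 0.44, adjusted p = 0.00122; median −0.64, camera adjusted p = 0.00261, and adjusted p = 0.0445 with an estimated correlation).

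**Figure D3:**
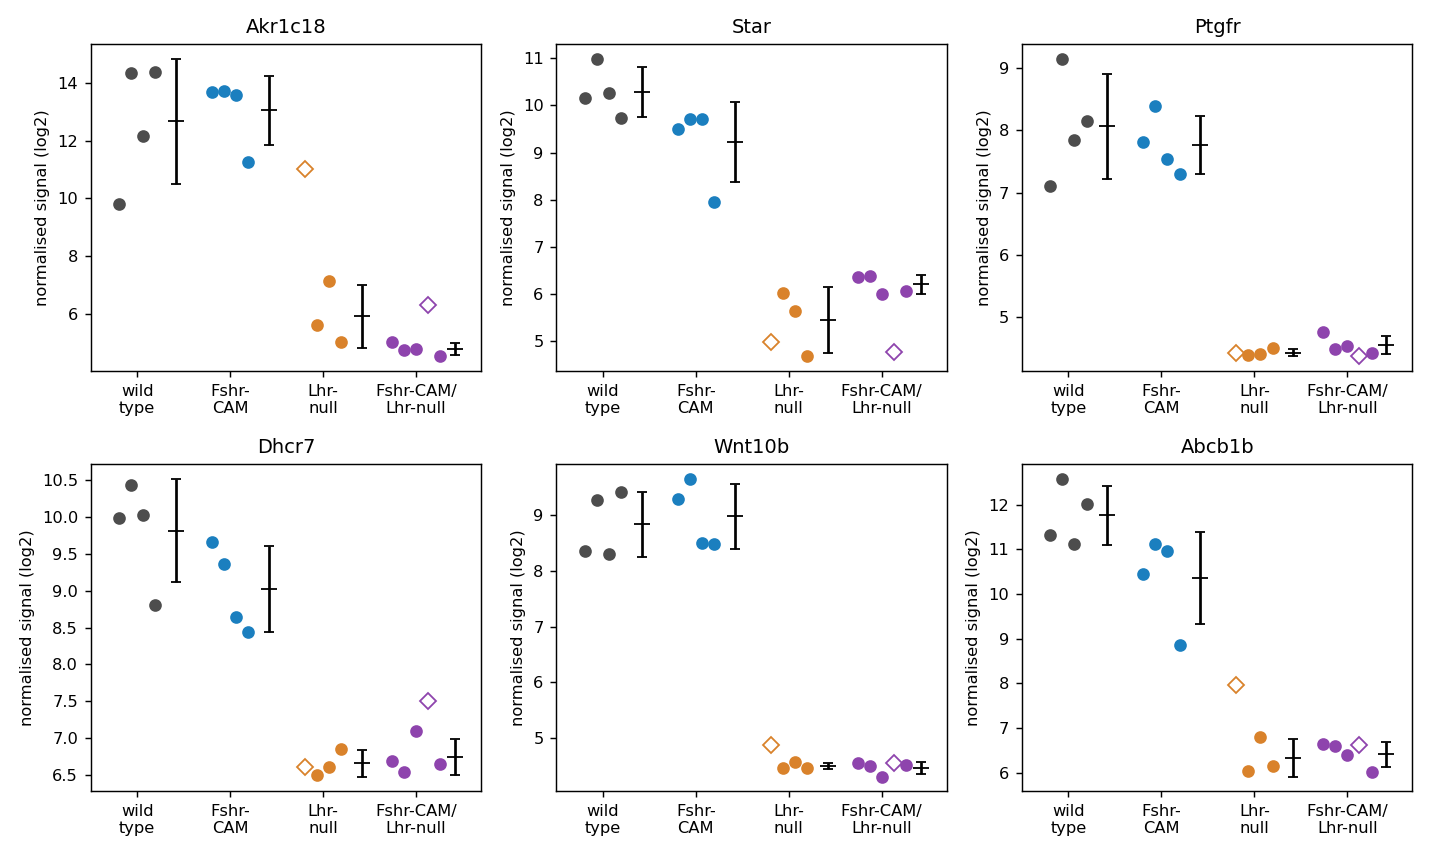
Normalised signal (log2, vertical axis) of Akr1c18, Star, Ptgfr, Dhcr7, Wnt10b and Abcb1b on each array in 4 genotypes; points are arrays, open diamonds are the arrays labelled Lhr-null replicate 1 and Fshr-CAM/Lhr-null replicate 4, and bars and whiskers are the mean and SD of the group's other arrays. Without the diamonds, Akr1c18 averages 12.68 in wild type and 5.93 in Lhr-null.

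Vessel and matrix genes were lower in Lhr-null. Of 15 endothelial genes 9 fell, and 12 adjusted over the list alone, among them the adhesion molecule Icam2 (−1.13 ± 0.25, adjusted p = 0.0078; list median −0.69, camera adjusted p = 5.89e-06, and adjusted p = 0.34 with an estimated correlation). Of 14 extracellular matrix genes 5 fell, and 6 adjusted over the list alone: Timp1, a metalloproteinase inhibitor (−2.69 ± 0.43), the collagen cross-linking enzyme Lox (−0.97 ± 0.17), and Tgfbi, Sparc and Col5a1, which were named after their values were seen (median −0.38, camera adjusted p = 0.00312, and adjusted p = 0.191 with an estimated correlation).

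Ciliated and oviduct genes and fat genes were higher in Lhr-null, on arrays of which replicates 3 and 4 carried high Ovgp1 and replicate 2 high sperm genes. Of 12 oviduct and ciliated epithelium genes 7 rose, and 9 adjusted over the list alone (median 2.42, camera adjusted p = 5.72e-09, and adjusted p = 0.0291 with an estimated correlation). Of 6 adipocyte genes 5 rose, both over all genes and adjusted over the list alone: Adipoq, the fat hormone adiponectin (2.72 ± 0.65, adjusted p = 0.0133), Cidea, and Lep, Cidec and Lpl, which were named after their values were seen (median 1.47, camera adjusted p = 0.000264, and adjusted p = 0.0288 with an estimated correlation).

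Follicle genes changed in both directions. Of 15 granulosa cell genes 5 rose, and 6 adjusted over the list alone: Inha (1.02 ± 0.14, adjusted p = 0.000306), Inhba (0.86), Hsd17b1, and Fst and Amhr2, which were named after their values were seen. The bile acid receptor Nr1h4 of the same list fell (−1.83 ± 0.35); the list's median was 0.53 (camera adjusted p = 0.00696, and adjusted p = 0.142 with an estimated correlation). Of 23 oocyte genes 2 rose, Kit, the stem cell factor receptor (1.88 ± 0.32, adjusted p = 0.00167), and Dazl, and 3 were higher adjusted over the list alone (median 0.65, camera adjusted p = 0.000169, and adjusted p = 0.557 with an estimated correlation). Of 14 cell proliferation genes 4 rose, Top2a (1.09 ± 0.28, adjusted p = 0.0189), Aurka, and Mcm2 and Mcm4, named after their values were seen, and 13 were higher adjusted over the list alone (median 0.72, camera adjusted p = 3.98e-06, and adjusted p = 0.377 with an estimated correlation). With Lhr-null replicate 1 included, the medians of the granulosa, oocyte, proliferation and cAMP lists had the opposite sign, and Inha (−0.27), Inhba (−0.37), Hsd17b1 (−0.24), Top2a (−0.12), Kit (1.26), Dusp1 (−1.72) and Adipoq (1.76) were not past the threshold.

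Of 12 theca and interstitial genes, Hhip (0.96) and Ptch1 rose and Fdx1 fell at least 1.47-fold (list median 0.05, camera adjusted p = 0.379). Of 12 genes of the LH-responsive ovulation list, the growth factor Btc rose (0.76) and the proteases Adamts1 (−1.07) and Adamts4 fell (list median −0.51, camera adjusted p = 0.211). Ptch1 and Adamts4 were named after their values were seen. Of 9 Sertoli cell genes, the transcription factor Sox9 (1.30 ± 0.26) and Dhh (1.08) rose (list median 0.49, camera adjusted p = 0.0582). The Sertoli list mean was 7.30 on Lhr-null replicate 2, the array with high sperm genes, and 6.66 and 6.68 on replicates 3 and 4. Wild type arrays stood at 6.36 to 6.56. Krt8 rose (0.83) of 9 surface epithelium genes, with 0 adjusted over the list alone (median 0.69, camera adjusted p = 0.121). The SD of Krt8 was 0.89 in Lhr-null and 0.07 in wild type. The surface epithelium list mean was 6.40, 6.87 and 7.62 on Lhr-null replicates 2, 3 and 4, against 6.43 to 6.87 in wild type. Whether RNA of other tissue on the Lhr-null arrays accounts for these rises was not tested. Irf7 fell (−0.87) of 7 interferon genes (median −0.12, camera adjusted p = 0.491). Limma called 0 macrophage, lymphocyte, red blood cell, smooth muscle and heat shock genes, with list medians of −0.44, 0.05, 0.40, 0.17 and −0.07 (camera adjusted p = 0.0575, 0.97, 0.804, 0.327 and 0.868).

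Fshr-CAM/Lhr-null against Fshr-CAM asks what loss of Lhr changes in the Fshr mutant. Akr1c18 fell (log2 fold change −7.99 ± 0.82 SE, n = 5 and 4, adjusted p = 5.11e-05), with its probe detected on 2 of 5 Fshr-CAM/Lhr-null arrays, and Star fell 9.96-fold (−3.32 ± 0.42, adjusted p = 0.00034). Ptgfr fell at least 6.94-fold (−3.27 ± 0.30, adjusted p = 3.34e-05), Onecut2 at least 24.4-fold (−4.99 ± 0.78) and Wnt10b at least 16.2-fold (−4.52 ± 0.27, adjusted p = 2.27e-07). The matricellular gene Ccn5 (−4.77 ± 0.48), the adhesion gene Nrcam (−4.49 ± 0.54, with 3 probes from −4.49 to −0.46) and Abcb1b (−3.90 ± 0.39) were among the largest falls. Fewer genes rose, among them Myh6 (at least 5.08-fold, 2.73 ± 0.41, adjusted p = 0.00193), Tnni2 (1.42) and Kit (1.27 ± 0.28, adjusted p = 0.0267). Fshr was not past the threshold (−0.36 ± 0.33, adjusted p = 0.623).

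With all 17 arrays, Bdh2 (1.20 ± 0.21, adjusted p = 0.00883) and Add3 (0.51 ± 0.10, adjusted p = 0.0174) rose and 89 genes fell. With 16 arrays 54 rose and 202 fell, of which 11 and 133 changed by over 2-fold, and with 15 arrays 25 rose and 170 fell. Leaving out Fshr-CAM replicate 2 from the 17 arrays gave 0 higher and 44 lower genes in limma, where 1157 genes had an unadjusted p under 0.05 with all 17.

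Of 10 corpus luteum genes 5 fell, Akr1c18, Ptgfr, Hsd17b7, Timp1 and Scarb1, the last named after its value was seen, and adjusted over the list alone 7 were lower and 1 higher (median −2.29, camera adjusted p = 1.79e-10, and adjusted p = 0.00398 with an estimated correlation). Of 12 steroid hormone synthesis genes 5 fell, Akr1c18, Star, Hsd17b7, Scarb1 and Cyp11a1, and 7 adjusted over the list alone (median −0.82, camera adjusted p = 9.55e-08, and adjusted p = 0.0122 with an estimated correlation). Of 18 cholesterol genes 3 fell, Hsd17b7 (8.27-fold), Dhcr7 and Fdps, the last named after its value was seen, and 12 adjusted over the list alone (median −0.67, camera adjusted p = 1.06e-10, and adjusted p = 0.121 with an estimated correlation). Of 16 cAMP genes Dusp1 (−2.08 ± 0.39) and Junb (−1.16 ± 0.20) fell, and 9 adjusted over the list alone (median −0.59, camera adjusted p = 9.39e-07, and adjusted p = 0.00529 with an estimated correlation). Kit was the called gene of 23 oocyte genes, with 17 higher adjusted over the list alone (median 0.94, camera adjusted p = 1.87e-08, and adjusted p = 0.368 with an estimated correlation). Without Fshr-CAM replicate 1 the median of list oocyte, Fshr-CAM/Lhr-null against Fshr-CAM, was 0.49 in the 17-array fit. Of 12 oviduct and ciliated genes limma called 0 (median 0.09, camera adjusted p = 0.426).

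The Lhr-null effects in the presence and absence of the Fshr mutation were compared across genes. Of the 837 genes lower in Lhr-null and the 202 lower in Fshr-CAM/Lhr-null, 182 were lower in both, where independent draws give 13.9, and 30 were higher in both, where independent draws give 2.97. Enc1 was the gene called in opposite directions, 0.54 and −0.72, and was named after its values were seen. With all 17 arrays 82 genes were lower in both. Pearson's r of the log2 fold changes was 0.667 with 16 arrays and 0.533 with 17; genes are not independent replicates.

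Fshr-CAM/Lhr-null against wild type gives the joint effect of both genotypes. Akr1c18 fell by 7.59 ± 0.82 on the log2 scale (n = 5 and 4, adjusted p = 4.34e-05), Fshr rose by 2.37 ± 0.33 (adjusted p = 0.000331) and Inhba rose by 1.56 ± 0.20 (adjusted p = 0.000226). Of 12260 genes 93 rose and 313 fell with all 17 arrays, 545 and 689 with 16, and 491 and 591 with 15; leaving out wild type replicate 2 from the 17 gave 23 and 178. Of 15 granulosa cell genes 6 rose, Fshr among them, and 1 fell, and 9 rose and 1 fell adjusted over the list alone (median 0.65, camera adjusted p = 8.99e-05, and adjusted p = 0.0291 with an estimated correlation). Of 18 cholesterol genes 13 fell, and 16 adjusted over the list alone (median −1.31, camera adjusted p = 1.8e-17, and adjusted p = 0.034 with an estimated correlation). Of 8 smooth muscle genes, which encode contractile proteins, Acta2, Myl9 and Myh11 rose, and 4 adjusted over the list alone (median 0.48, camera adjusted p = 0.00263, and adjusted p = 0.404 with an estimated correlation); these 3 were named after their values were seen.

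Fshr-CAM/Lhr-null against Lhr-null asks what the Fshr mutation changes where Lhr is lost. Fshr was not past the threshold with 16 arrays (1.56 ± 0.36, adjusted p = 0.0587). With 15 arrays, which leave out Fshr-CAM/Lhr-null replicate 4 because of its low Fshr, so that the Fshr p-values of that fit depend on this choice, Fshr was 3.77-fold higher (log2 signal 11.54 ± 0.14 against 9.62 ± 0.41, SD, n = 4 and 3; log2 fold change 1.92 ± 0.22 SE, adjusted p = 0.000313), and probe ILMN_2736929 was higher by 1.53 ± 0.22 (adjusted p = 0.00245) while ILMN_2932141 was not past the threshold (−0.55 ± 0.22, adjusted p = 0.227). In the same fit Rhox8 rose (1.85 ± 0.34, adjusted p = 0.0106), as did the BMP antagonist Grem1 (1.56 ± 0.34, adjusted p = 0.0285) and Cyp11a1 (1.38 ± 0.23, adjusted p = 0.00583, with 3 probes from 0.24 to 1.56). The largest rises were of Asgr1, a glycoprotein receptor (2.52 ± 0.57), Lrp11 (2.08 ± 0.36), the dipeptidase Dpep1 (2.05 ± 0.32), the chemokine receptor Ackr1 (at least 2.79-fold, 2.00 ± 0.33) and Adam23 (1.95 ± 0.37). With 16 arrays Grin2b (1.53 ± 0.33, adjusted p = 0.0419) and the secreted protein C1qtnf1 (0.97 ± 0.17, adjusted p = 0.0116) were among those that rose.

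Cilia genes, whose list mean was 7.20, 7.19, 7.24 and 8.44 on Lhr-null replicates 1 to 4, fat genes and the sperm genes Prm1 and Tnp1 fell in Fshr-CAM/Lhr-null against Lhr-null. The spermatid list mean was 8.44 on Lhr-null replicate 2 and 5.23 and 5.44 on replicates 3 and 4, against 4.67 to 5.15 in wild type. With 16 arrays the falls included Prm1 (−5.14 ± 0.94, adjusted p = 0.015), Dynlrb2 (−4.98 ± 0.48, adjusted p = 4.95e-05), Rsph1 (−4.04) and Tnp1 (−3.18). Of 12 oviduct and ciliated genes 6 fell, and 7 adjusted over the list alone (median −2.19, camera adjusted p = 2.66e-14, and adjusted p = 0.00866 with an estimated correlation). Of 6 adipocyte genes Cidea (−1.60) and Cidec (−1.55) fell, and 4 adjusted over the list alone (median −1.39, camera adjusted p = 2.14e-05, and adjusted p = 0.0122 with an estimated correlation). Limma called 0 of 15 granulosa cell genes with 16 arrays (2 adjusted over the list alone, median 0.17, camera adjusted p = 0.278).

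With all 17 arrays 19 genes rose and 69 fell in this comparison. With 16 arrays 16 rose and 69 fell, of which 52 were also called with 17, and with 15 arrays 147 rose and 139 fell, of which 83 were also called with 16. From the 17 arrays, leaving out Fshr-CAM/Lhr-null replicate 1 gave 2 higher genes and leaving out replicate 4 gave 84. Leaving out Lhr-null replicate 4 gave 33 lower genes and leaving out replicate 3 gave 119.

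The genes that the Fshr mutation raised with and without Lhr were compared in the 15-array fit. Of 38 and 147 higher genes 17 were shared, where independent draws give 0.463. Besides Fshr and Rhox8 they included Fam162b (2.14 with Lhr and 1.69 without), Ackr1 (1.83 and 2.00), Grem1 (1.72 and 1.56), Masp1, a complement protease (1.46 and 1.24, with 3 probes from −0.13 to 1.24 without Lhr), the metallothionein Mt3 (1.29 and 1.14) and the vessel ligand Angpt2 (1.03 and 1.13); Mt3 and Angpt2 were named after their values were seen. Of 5 and 139 lower genes 1 was shared (A730049H05Rik, named after its values were seen, −0.99 and −0.88), and 0 genes were called in opposite directions in limma. Among genes called with 17 arrays 0 were shared, and with 16 arrays 1, Masp1. Pearson's r across all genes was 0.167 with 15 arrays and 0.139 with 17.

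**Figure D4:**
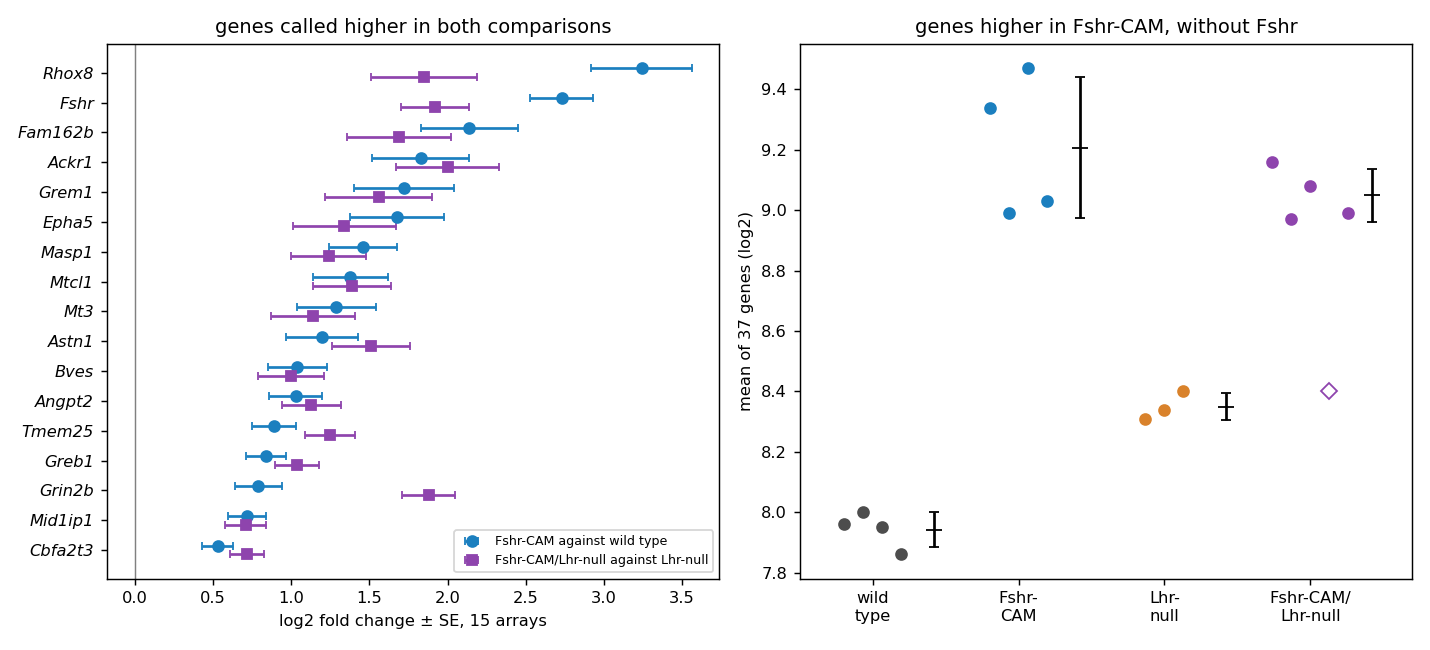
Left: log2 fold change and SE of 17 genes higher in Fshr-CAM against wild type and in Fshr-CAM/Lhr-null against Lhr-null in the 15-array fit. Right: mean normalised signal (log2) on each array of 37 genes called higher in Fshr-CAM than in wild type with 15 arrays, Fshr left out. That choice fixes the difference between wild type and Fshr-CAM arrays. Genes of the left panel other than Fshr are among the 37. Points are arrays, the open diamond is the array labelled Fshr-CAM/Lhr-null replicate 4, and bars and whiskers are the mean and SD of the group's other arrays. That array lies at 8.40 and the other Fshr-CAM/Lhr-null arrays at 8.97 to 9.16.

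The interaction asks whether the effect of the Fshr mutation differs where Lhr is lost, which bears on the crosstalk of the gonadotropin pathways that the series title names. In the 15-array fit Inha was lower than the sum of both effects (−0.99 ± 0.19 SE, adjusted p = 0.0325), with mean log2 signals of 12.91 in wild type, 13.72 in Fshr-CAM, 13.93 in Lhr-null and 13.75 in Fshr-CAM/Lhr-null. Cyp11a1 was higher than that sum (1.76 ± 0.32, adjusted p = 0.0242), as were Adam23 (3.17 ± 0.50, adjusted p = 0.0121), Dpep1 (2.48 ± 0.44, adjusted p = 0.024), Ch25h, a cholesterol hydroxylase (2.20 ± 0.44, adjusted p = 0.0392), Pkdcc (1.59) and Enox1 (1.55). None of these 15-array calls, Inha included, was past the threshold with 16 or 17 arrays. The 15-array fit leaves out Fshr-CAM/Lhr-null replicate 4, a choice made after the data were seen. Residuals were reassigned for 17 and 16 arrays only, so the 15-array calls have no chance count. With 16 arrays cilia genes had the largest negative interactions among named genes, such as Dynlrb2 (−5.05 ± 0.66, limma adjusted p = 0.00254). With 15 arrays the largest were of Dynlrb2 (−5.01) and Pebp4 (−3.78), the latter not of the oviduct and ciliated list. The interaction of Fshr was not past the threshold with 16 arrays (−1.17 ± 0.50, adjusted p = 0.626) or 15 (−0.82 ± 0.30, adjusted p = 0.346).

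With all 17 arrays the interaction was positive for 0 genes in limma and negative for 13, with 706 at an unadjusted p under 0.05. With 16 arrays it was positive for 0 and negative for 24, with 894 at an unadjusted p under 0.05, and with 15 arrays positive for 22 and negative for 45. Leaving out Fshr-CAM replicate 2 from the 17 arrays gave 6 negative genes, and leaving out Lhr-null replicate 1 gave 24. Of 12 oviduct and ciliated genes 4 were negative with 16 arrays (Dynlrb2, Dnali1, Tekt1 and Ccdc39, the last named after its value was seen) and 7 adjusted over the list alone (median −2.25, camera adjusted p = 2.66e-14, and adjusted p = 0.00866 with an estimated correlation). Of 15 granulosa cell genes 0 passed and 2 were lower adjusted over the list alone (median −0.49, camera adjusted p = 0.00019, and adjusted p = 0.0349 with an estimated correlation). With all 17 arrays the median of the granulosa cell list was 0.42 (camera adjusted p = 0.314), and with 15 arrays −0.33 (camera adjusted p = 0.000239, and adjusted p = 0.0762 with an estimated correlation).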

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

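The tests on single arrays and on cilia and sperm genes were chosen after the results were seen, except the test of the label of Fshr-CAM/Lhr-null replicate 4, which was written before its result; the splits of the samples were planned.

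Pituitary genes mark the array labelled Lhr-null replicate 1, where 8 gene lists and 20 named genes stood apart from the group and 388 probes were detected that no other array detected. On this array 248 genes were at least 8-fold above every other array, where the most on any other array was 108, on Lhr-null replicate 2. This count cannot decide on poor RNA or low signal, since RNA of another tissue can give such genes at any quality. Probes detected at p under 0.05 numbered 19366 here and 20301 to 22006 on the other arrays. Loss of Lhr is argued against by the other Lhr-null arrays, whose pituitary genes differed from wild type by a median of 0.03. Gh, Pomc, Prl, Cga, Lhb and Tshb stood at 14.90, 14.86, 14.71, 14.52, 14.40 and 13.79 on this array, and of 8 further pituitary genes, whose values had not been seen when they were listed, 7 were at least 2-fold above every other array. A candidate explanation is RNA of the pituitary gland on this array. All 15 pituitary list genes were detected here at p under 0.05, against 0 to 3 on each other array. Of 16 granulosa cell genes 8 were detected, and of 24 oocyte genes 12. The Fshr probes stood at 4.51, 4.67 and 4.43, all with a detection p above 0.05. Whether the sample is wrong or mixed stays open.

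Fshr was low on the array labelled Fshr-CAM/Lhr-null replicate 4, at 9.71 for probe ILMN_1228881 and 5.58 for ILMN_2736929, where 14 named genes stood apart. Fewer granulosa cells are argued against by the other granulosa cell genes, whose median difference from the other arrays of the group was 0.12. The mean of 37 other genes higher in Fshr-CAM than in wild type was 8.40 on this array, equal to the highest of the 8.31 to 8.40 of Lhr-null replicates 2 to 4 and below the 8.97 to 9.16 of the other arrays of its group. The sample may lack the Fshr mutation, as with a wrong label; a mutation that was present but not active in this animal was not tested. The steroid list mean of this array, 7.36, and its spermatid list mean, 4.97, also stood apart.

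Cilia genes were high on all 4 Lhr-null arrays, with list means of 7.20, 7.19, 7.24 and 8.44 against 5.46 to 5.61 in wild type. The first of these values is of replicate 1, the array marked by pituitary genes. Sperm genes were high as a list on replicate 2, with a spermatid list mean of 8.44 there and 5.23 and 5.44 on replicates 3 and 4. Loss of Lhr whatever the Fshr genotype is argued against by 7 cilia genes with a median of 3.43 in Lhr-null against wild type and 0.13 in Fshr-CAM/Lhr-null against Fshr-CAM. On replicate 2 oviduct tissue with the profile of replicate 3 or 4 is argued against: Ovgp1 was 6.77 there, within the wild type range of 6.23 to 7.42, and differed by −3.67 (Dynlrb2 at the ratio of replicate 3, which needs 10.43) to −8.58 from the level needed by each of the 7 cilia genes. In addition 7 of 10 spermatid genes unseen when listed were at least 2-fold above every other array, with Ldhc at 13.30 and Odf1 at 9.72, and testicular germ cell RNA may be on this array, where the Y-linked genes Uty, Kdm5d and Eif2s3y were at 4.65, 4.58 and 4.69, near background. On replicates 3 and 4 oviduct tissue may be present, with Ovgp1 at least 3.88 above every wild type and Fshr-CAM array; an effect of Lhr loss that needs the unmutated Fshr stays open and was not tested.

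On Lhr-null replicate 2, 442 probes were detected that no other array detected. The mean of the oviduct and ciliated list stood apart on Lhr-null replicate 4 at 8.44 and on Fshr-CAM/Lhr-null replicate 3 at 6.27. The theca list mean of wild type replicate 2 was far from its group at 8.52. Pituitary list means of wild type replicate 2 and Fshr-CAM replicate 3 were far from their groups at 4.53 and 4.44, both near background. Probe ILMN_2932141 of Fshr stood apart on Fshr-CAM replicate 4 at 9.64.

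Named genes far from their group numbered 1 on wild type replicate 2, 3 on wild type replicate 4, 2, 1 and 4 on Fshr-CAM replicates 1, 3 and 4, 1, 5 and 1 on Fshr-CAM/Lhr-null replicates 1, 3 and 5, and 1 each on Lhr-null replicates 3 and 4. Chance puts a sample apart in about 1 of 20 groups; among 400 tests on 100 named genes 54 did so, and among 116 tests on lists and Fshr probes 21 did so.

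Several genes passed the interaction test, which for cilia genes does not separate the Fshr mutation from tissue carried on the Lhr-null arrays; clone and predicted names are left out here. With 17 arrays the largest of 13 were the cilia genes Dynlrb2 (−5.20), Mdh1b (−3.99), Spag6l (−3.61), Fam166c (−3.47), Tekt1 (−3.19) and Ccdc113 (−3.18). Mdh1b, Spag6l, Fam166c and Ccdc113 were at background on every array outside Lhr-null, so their values are fitted and no bounds. With 16 arrays the largest of 24 were Dynlrb2 (−5.05), Dnali1 (−3.77), Cfap299 (−3.58), Pifo (−3.48), Tekt1 (−2.96) and Spaca9 (−2.75). With 15 arrays, of 22 positive and 45 negative genes, the largest were Adam23 (3.17), Dpep1 (2.48), Ch25h (2.20), Cyp11a1 (1.76), Pkdcc (1.59) and Enox1 (1.55) on the positive side and Dynlrb2 (−5.01), Pebp4 (−3.78), Dnali1 (−3.75), Rsph1 (−3.65), Pifo (−3.63) and Cfap299 (−3.54) on the negative side; Inha (−0.99), of the granulosa cell list, was also negative.

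Gene lists with an interaction by camera at the preset correlation had these medians with 17 arrays: theca 0.71, steroid hormone synthesis 0.55, cholesterol 0.56, oocyte 1.18, red blood cell −1.26, endothelial 0.42, oviduct and ciliated −1.87, adipocyte −1.08, extracellular matrix 0.72 and cAMP −0.54. With an estimated correlation the oviduct list (adjusted p = 0.00733) and the adipocyte list (adjusted p = 0.0205) were kept, and the others had an adjusted p of 0.444 to 0.752. With 16 arrays the medians were granulosa −0.49, cholesterol 0.53, endothelial 0.38, oviduct and ciliated −2.25, adipocyte −1.51, extracellular matrix 0.34 and proliferation −0.20. With an estimated correlation the granulosa (adjusted p = 0.0349), oviduct (adjusted p = 0.00866) and adipocyte (adjusted p = 0.00529) lists were kept, and the others had an adjusted p of 0.214 to 0.678.

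Other splits of the same arrays were counted for each comparison, and chance is called excluded where under 0.05 of the splits, the real one included, called as many genes. For Fshr-CAM against wild type chance cannot be excluded: the real split called 6 genes with 17 arrays and the highest other split 14, and 25 and 50 with 16 arrays, where the split with 50 exchanged Fshr-CAM replicates 2 and 3 with wild type replicates 1 and 3. This concerns the counts alone: Fshr separated the groups, at 11.10 or above against 9.14 or below. At an unadjusted limma p under 0.001, 12 genes were higher in both comparisons of the Fshr mutation in fits with no array in common. Independent draws give 0.469. Those fits left out Lhr-null replicate 1 and Fshr-CAM/Lhr-null replicate 4, the latter for its low Fshr, after the data were seen. The 12 shared genes thus depend on that choice. Among genes past the adjusted threshold, 0 were shared as higher with 17 arrays and 1 with 16. For Lhr-null against wild type chance is excluded, with 861 genes against 78 with 17 arrays and 1505 against 325 with 16. For Fshr-CAM/Lhr-null against Fshr-CAM it is excluded, with 91 against 1 and 256 against 6, and against wild type with 406 against 20 and 1234 against 282. For Fshr-CAM/Lhr-null against Lhr-null it is excluded by this share, although 1 other split called more genes, with 88 genes for the real split and 106 for the highest other with 17 arrays, and 85 and 107 with 16. That other split put Fshr-CAM/Lhr-null replicate 4 with the Lhr-null arrays with 17 arrays, and replicates 4 and 5 with 16. The larger group holds 5 arrays, so a split with all Lhr-null arrays in it must add others. The split therefore does not test the label of replicate 4.

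For the interaction the residuals of a fit without it were reassigned among the arrays in place of splits. The real count was 13 genes with 17 arrays and the highest other 383, several times the real count, which points to a structure of the samples. Without Lhr-null replicate 1, which stands apart, the counts were 24 and 63. Part of the structure thus goes with that array, and the rest was not identified. As many genes were called in 2 of 100 reassignments with 17 arrays and in 3 of 100 with 16, the real count included. Both shares are under 0.05. The reassignment takes the arrays as exchangeable, which this structure of the samples goes against, so the shares cannot exclude chance.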

How the results depend on the processing

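Leaving out both doubted arrays (15 arrays) and Lhr-null replicate 2 as well (14 arrays) were chosen after the data were seen; the other alternatives were planned. The slide block was not run, as no slide is given in the sources used here, and the interaction uses the arrays of every group. The cause was not tested for any result that moved, beyond the fewer arrays that an alternative uses. Signal over background limits folds against a group at background, which are given as bounds in comparisons of 2 groups; interactions of such genes are fitted values.

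Luteal, steroid and cholesterol genes kept lower medians in Lhr-null against wild type under every alternative run. The corpus luteum and cholesterol medians ranged from −3.41 to −2.61 and −1.60 to −1.17, and the median of list steroid hormone synthesis, Lhr-null against wild type, from −2.39 to −0.99. Of 1456 gene values, 1164 kept direction and side of the threshold, 128 lost it, 153 gained it and 11 reversed. Of 625 list medians, 543 were kept, 40 lost the threshold, 21 gained it and 21 reversed. In fits without 1 array, of 2293 gene values 2051 were kept, 184 lost the threshold, 55 gained it and 3 reversed, and of 1071 list medians 988, 50, 24 and 9. Both correlations of effects across genes stayed positive, with ranges without 1 array of 0.105 to 0.164 for Fshr-CAM and 0.452 to 0.667 for Lhr-null.

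Counts are given as higher and lower, against those of 17 arrays. The authors' quantile-normalised values and the series matrix each gave 0 lower in Fshr-CAM against wild type, 11 higher in Fshr-CAM/Lhr-null against Lhr-null and 7 negative interactions. Median-centred signals gave 0 lower in Fshr-CAM, 896 lower in Lhr-null, 3 higher in Fshr-CAM/Lhr-null against Lhr-null, 1 and 201 against Fshr-CAM, and 17 and 570 against wild type. Median centring moved the median of all genes to −0.111 in Lhr-null against wild type and −0.121 in Fshr-CAM/Lhr-null against Fshr-CAM, from −0.014 and 0.023. No detection filter gave 0 lower in Fshr-CAM and 10 higher in Fshr-CAM/Lhr-null against Lhr-null, where the strict filter gave 31 and the mean of probes 32, with 1 positive interaction.

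Array weights without a trend gave 30 and 18 in Fshr-CAM, 752 and 1004 in Lhr-null, 211 and 231 in Fshr-CAM/Lhr-null against Lhr-null, 95 and 294 against Fshr-CAM, 913 and 1069 against wild type, and 32 and 84 interactions. The replicate block gave 0 lower in Fshr-CAM, 3 and 43 in Fshr-CAM/Lhr-null against Lhr-null, 0 and 38 against Fshr-CAM, 33 and 190 against wild type, and 4 negative interactions; of 21 pairs of arrays with the same number 4 correlated above 0.1, with a range of −0.467 to 0.321, so the numbers do not pair the arrays. Only the arrays compared gave 6 and 0, 48 and 139, 0 and 11, 29 and 206, and 603 and 670 in these comparisons.

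With 15 arrays the counts were 38 and 5, 784 and 896, 147 and 139, 25 and 170, 491 and 591, and 22 and 45 for the interaction. With 14 arrays they were 39 higher in Fshr-CAM, 659 higher in Lhr-null, 104 and 129, 30 and 176, 520 and 606, and 18 and 44.

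Without 1 array, Fshr-CAM against wild type gave 1 (without wild type replicate 2) to 21 (without Lhr-null replicate 1) higher and 0 to 8 (without wild type replicate 4) lower. Lhr-null gave 146 to 668 and 315 to 837. Fshr-CAM/Lhr-null against Lhr-null gave 2 to 84 and 33 to 119, against Fshr-CAM 0 to 54 and 44 to 202, and against wild type 23 to 545 and 178 to 689. The interaction gave 0 to 2 and 6 to 24.

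Follicle genes reversed in Lhr-null against wild type once Lhr-null replicate 1 was out. Without that array, with 15 and with 14 arrays, Hsd17b1 was 1.07, 1.07 and 1.23, Dhh 1.08, 1.08 and 1.19, and Top2a 1.09, 1.09 and 1.18; Fshr was 0.82 and 1.05 with 15 and 14, and Dhh 0.98 with array weights. The range without 1 array began at −0.78 for Hsd17b1, −0.50 for Dhh and −0.61 for Top2a. The interaction of Inha was −0.99 and −1.08 with 15 and 14. In the same 3 fits the list medians were 0.53, 0.53 and 0.68 for granulosa, 0.65, 0.65 and 0.78 for oocyte, 0.72, 0.72 and 0.82 for proliferation, and −0.64, −0.64 and −0.59 for cAMP; the other ends of their ranges without 1 array were −0.78, −0.66, −0.50 and 0.26.

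In Fshr-CAM/Lhr-null against Lhr-null the reversed medians were −0.26, −0.39 and −0.48 for proliferation and 0.11, 0.19 and 0.19 for cAMP, which was 0.12 with array weights, and −0.02 for granulosa with 14 arrays. For the interaction they were −0.49, −0.33 and −0.44 for granulosa, −0.20, −0.34 and −0.46 for proliferation, 0.02, 0.04 and 0.01 for cAMP, and −0.03 for oocyte with 14 arrays. The other ends of the ranges without 1 array were 0.90 for proliferation and −0.80 for the median of list cAMP response and immediate early, Fshr-CAM/Lhr-null against Lhr-null, and 0.75, 0.96 and −0.78 for granulosa, proliferation and cAMP in the interaction.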

Other observations

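Genes were chosen here after their values were seen, and values are from the 16-array fit unless stated. Enc1, an actin-binding adaptor, Ddit4, an inhibitor of mTOR signalling, and Gata6, a transcription factor of granulosa cells, rose with the Fshr mutation where Lhr was present, by 1.42 ± 0.15, 1.11 ± 0.13 and 0.58 ± 0.10 on the log2 scale (limma, n = 4 and 4, adjusted p = 0.000827, 0.00143 and 0.021). Where Lhr was lost their changes were 0.16 ± 0.15, −0.01 ± 0.14 and −0.26 ± 0.11, none past the threshold. This fit keeps Fshr-CAM/Lhr-null replicate 4, whose label is in doubt. With all 17 arrays the mean log2 signal of Enc1 was 9.09 in wild type and 9.5 in Lhr-null. That of Ddit4 was 8.93 and 9.7. The interaction of these genes includes this difference between Lhr-null and wild type. The interaction test was past it for Enc1 (−1.26 ± 0.21, adjusted p = 0.0211), Ddit4 (−1.12 ± 0.19, adjusted p = 0.0209) and Gata6 (−0.84 ± 0.15, adjusted p = 0.0258).

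In Fshr-CAM/Lhr-null against wild type, Insl3, the hormone of theca cells, rose (2.02 ± 0.60 SE, n = 5 and 4, adjusted p = 0.0425), and so did Gpnmb of the macrophage list (1.75 ± 0.53, adjusted p = 0.0469). Rgcc, a cell cycle regulator of the LH-responsive ovulation list, fell (−1.39 ± 0.35, adjusted p = 0.0214). In Lhr-null against wild type Insl3 was not past the threshold (1.68 ± 0.68, adjusted p = 0.116), and its interaction was 0.55 ± 0.91 (adjusted p = 0.944).

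The genes shared by both comparisons of the Fshr mutation were also counted in fits that had no array in common. With 15 arrays, wild type and Fshr-CAM alone gave 46 higher genes and Lhr-null and Fshr-CAM/Lhr-null alone gave 123 at an unadjusted limma p under 0.001. Of these 12 were higher in both, where independent draws give 0.469, and 0 were called in opposite directions.

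The sperm gene Prm1 was above the level of most arrays on further samples. It stood at 8.72 and 7.70 on wild type replicates 3 and 4, 7.98 on Fshr-CAM replicate 4, 6.40 on Fshr-CAM/Lhr-null replicate 4, and 9.63, 8.98 and 10.22 on Lhr-null replicates 1, 3 and 4. On the remaining arrays other than Lhr-null replicate 2 it was 4.58 to 5.43.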
